A study of Mus musculus with 4 samples.

How the data were processed

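Th17 cells of C57BL/6 mice were cultured for 48 h with vehicle or with recombinant mouse SAA1, labelled as 2 ng/ml, and total RNA was made into Illumina TruSeq libraries, per the labels' protocols. The 4 libraries were grouped by their titles, 2 as vehicle and 2 as SAA1. The control libraries carry the treatment label none and the abbreviation veh in their titles, read here as vehicle. TopHat2 and Cuffdiff are named, without versions, in the submitters' processing notes, and so are the genome builds mm9 and mm10. Their settings for library type, filtering and scaling between libraries are not given in the sources used here.

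A single table was analysed, in the layout of Cuffdiff's table of gene differences per the file headers. It holds, for each gene row, the locus, a test status and a value in FPKM per group, which the authors' Cuffdiff run made from both libraries of the group. A test statistic, which is a score of the log ratio over its standard error, was deposited for each tested gene. The deposited p-value and q-value of each gene are the authors' own, and the smallest p in the table is 5e-05, shared by 300 genes. Of 23356 rows, 11481 had the status of tested, 11874 were not tested by the authors and 1 had too many fragments. No row gives values per library, so replicates could not be compared with each other, and whole reads could not be recovered from the FPKM values. Depth is therefore unknown, and no interval from counts is given.

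The deposited log2 column holds spreadsheet errors in place of some values, so each log2 ratio was recomputed as SAA1 FPKM over vehicle FPKM. A standard error was taken as that ratio divided by the deposited test statistic; its median was 0.22 on the log2 scale. The deposited q-value was checked as the Benjamini-Hochberg adjustment of the deposited p over tested rows, with a largest gap of 5.23e-07. In 27 rows a spreadsheet had turned the gene symbol into a date; none of them was called, and they were left out of the lists. Of 21458 rows whose symbol is in the GRCm38 gene table, 99.0% had a locus overlapping the GRCm38 position, so coordinates are given on mm10, which is that assembly, with starts counted from 1. A total of 4346 rows share a locus with another row, 75 of them called, and the values of overlapping genes are uncertain where reads could belong to either. Near-identical copies carry the same doubt, and strand settings are not given in the sources used here.

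The tests were fixed before the data were examined. They foresaw limma on log2 FPKM values or a count test had values per library been given. With group values only, the authors' test as deposited was the main test, with a gene called at an adjusted p under 0.05. The replicate block, the omission of each replicate and the alternatives for counts or for FPKM per library were foreseen only for a table with values per library and were not run. The genes named were fixed by rule. They are the 10 largest increases and 10 largest decreases among called genes with at least 1 FPKM in either group, 15 genes of T helper biology whatever their values, and up to 4 members of each list, called members by smallest adjusted p and then by fold. Where fewer than 2 were called, the members with the largest fold were taken. Cd5l, Lef1, Ctss, Lyz2, C1qa, Fpr2, Scarb1, Myd88, Tnf, Cdk1, Saa1, Saa2, S100a9 and Hba-a2 and the genes named only in the closing section lie outside the rule and were chosen after their values were seen. Some genes that the rule names are not reported here.

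In all, 24 gene lists were fixed before the data were examined. For each, members called higher, called lower and not called were counted, with the adjustment over all tested genes and with the adjustment over the list alone. The log2 ratio of FPKM plus a pseudocount of 0.1 was taken over members with at least 1 FPKM in either group, which understates the change of weakly expressed genes. The list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list with at least 3 such members stood apart below percentile 2.5 or above percentile 97.5. On simulated data made by shuffling the log2 ratios of SAA1 against vehicle over 10701 genes, 4.5% of 200 lists of 16 genes stood apart with no shift, and 100% with a shift of 0.5. Shuffling removes any link between genes, so the 4.5% holds for lists of unrelated genes. Other list sizes and other shifts were not simulated, so the 100% does not apply to smaller lists or smaller shifts.

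Alternatives covered the threshold on the adjusted p (0.01 and 0.1), a fold minimum of 1.5, an expression minimum, recomputed adjustments, centring on the median, the pseudocount (1), the minimum for lists (5 and 0.1 FPKM), unmatched random lists and the mean over members. Added after the data were seen were a two-sided normal p of the deposited statistic, the removal of rows that share a locus and the removal of microRNA and small nucleolar RNA rows from the random lists. Pseudogene copies were counted by aligning the first annotated coding transcript of each ribosomal protein gene and of Gapdh to 13607 pseudogene transcripts of the GENCODE M21 annotation, with at least 95% identity over at least 100 bases. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and BLAST+ 2.17.0.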

Results

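T helper 17 (Th17) cells are CD4 T cells defined by the production of IL-17 cytokines. RNA was sequenced from Th17 cells of C57BL/6 mice after 48 h in culture, in 4 libraries. Of these, 2 came from cells given vehicle and 2 from cells given recombinant mouse serum amyloid A1 (SAA1), an acute-phase protein made by the liver and by the gut epithelium. The dose is 2 ng/ml as labelled, and its unit could not be checked against another source. The series concerns a circuit in which epithelial serum amyloid A acts on local Th17 responses, and the comparison asks which transcripts of Th17 cells differ when SAA1 is present in culture. Expression is given as the authors' value for each group in FPKM (fragments per kilobase of transcript, scaled to the fragments mapped). The authors' deposited table lists 23356 gene rows, of which 10701 had at least 1 FPKM in either group and 11481 were tested. The number of reads per library is unknown, and no spread between libraries can be given because each group has a single value.

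Transcripts of the cytokines that define Th17 cells, and of a chemokine they make, were higher with SAA1. Il17a, which encodes IL-17A, rose from 56.0 to 568 FPKM, a 10.1-fold difference with a log2 ratio of 3.34 ± 0.21 (SE implied by the authors' test statistic). Il17f, its neighbour on chromosome 1, rose from 145 to 898 FPKM (6.21-fold, log2 ratio 2.64 ± 0.20). Ccl20, the chemokine that attracts cells bearing Ccr6, rose from 12.7 to 209 FPKM (16.6-fold, log2 ratio 4.05 ± 0.25). Il22, a cytokine that acts on epithelial cells, fell instead, from 1.59 to 0.348 FPKM (log2 ratio -2.19 ± 0.71). In the authors' deposited table the adjusted p was 0.0019 for Il17a, Il17f and Ccl20, which is the smallest value it holds, and 0.027 for Il22.

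By the adjusted p of the authors' deposited table at a threshold of 0.05, 749 genes (6.52% of those tested) were called, 456 higher and 293 lower with SAA1. The median log2 ratio of the called genes was 0.80 among the higher and -0.72 among the lower. At least 2-fold changes numbered 164 higher and 70 lower, and at least 4-fold changes 34 higher and 6 lower. At an unadjusted p under 0.05 the table holds 1819 genes. The median log2 ratio over all expressed genes was -0.02, after a scaling by the authors that is not given in the sources used here, so a shift of all genes could not be seen.

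**Figure D1:**
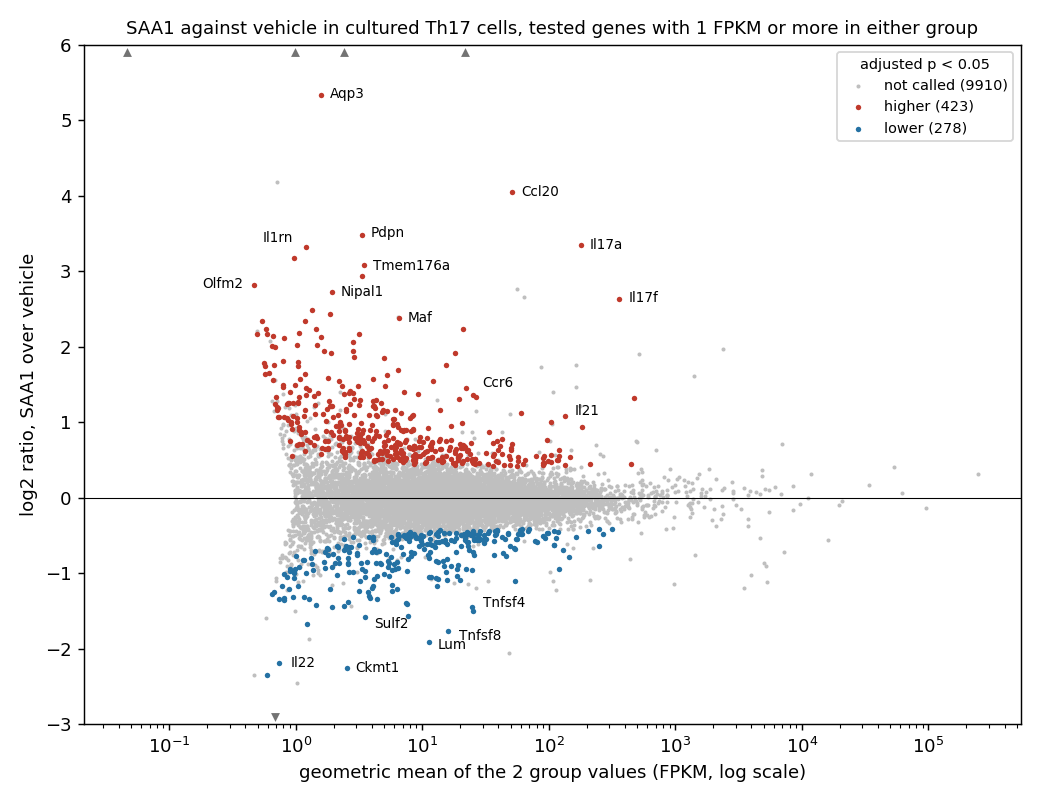
Each point is a gene with at least 1 FPKM in either group, tested by the authors and above 0 in both groups (10611 genes), with the geometric mean of the vehicle and SAA1 values in FPKM on a log axis and the log2 ratio of SAA1 over vehicle on the vertical axis. Among them 423 were called higher (red) and 278 lower (blue), with Aqp3 at 5.34 highest of the red points and Il17a at 3.34 and Il17f at 2.64 far above other genes of their level, while triangles at the edges mark 5 genes that were not called and lie outside the range drawn.

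Among the 10 largest increases, Aqp3, a channel for water and glycerol, rose from 0.249 to 10.1 FPKM (log2 ratio 5.34 ± 0.62). Pdpn, which encodes the membrane glycoprotein podoplanin, rose from 0.993 to 11.1 FPKM (3.48 ± 0.37), and Il1rn, the IL-1 receptor antagonist, from 0.380 to 3.80 FPKM (3.32 ± 0.52). The adjacent genes Tmem176a and Tmem176b rose together, from 1.19 to 10.1 and from 1.20 to 9.19 FPKM. Fbxo2, Olfm2 and Nipal1 had log2 ratios of 3.18, 2.82 and 2.72. The adjusted p in the authors' deposited table was 0.0019 for these genes except Olfm2 (0.020).

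The 10 largest decreases held a pair of TNF family ligands. Tnfsf8, the CD30 ligand, fell from 29.4 to 8.66 FPKM (log2 ratio -1.76 ± 0.22) and Tnfsf4, the OX40 ligand, from 40.9 to 15.0 FPKM (-1.45 ± 0.22). Trat1, an adaptor of the T cell receptor complex, fell from 42.7 to 15.1 FPKM (-1.50 ± 0.25), and Lum, the matrix proteoglycan lumican, from 22.0 to 5.83 FPKM (-1.91 ± 0.24). Ckmt1, a mitochondrial creatine kinase whose locus overlaps another gene row, fell from 5.52 to 1.15 FPKM. Arrdc3, Sulf2, BC064078 and 4930506M07Rik had log2 ratios of -1.57, -1.58, -1.67 and -2.35. In the authors' deposited table the adjusted p was 0.045 for BC064078 and 0.0019 for the others named here.

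Beyond the effector cytokines, some receptors and transcription factors of the Th17 programme rose by smaller amounts, and others were not called. Ccr6, the receptor of Ccl20, rose from 15.8 to 40.6 FPKM (log2 ratio 1.36 ± 0.23). Il21, a cytokine that sustains Th17 cells, rose from 92.8 to 196 FPKM (1.08 ± 0.20), and Il23r, the IL-23 receptor, from 7.32 to 10.5 FPKM (0.52 ± 0.23). Maf, a transcription factor of Th17 cells, rose from 2.87 to 14.9 FPKM (2.37 ± 0.25). Of the 21 tested members of the Th17 list, 9 were called higher, 1 lower (Il22) and 11 not at all by the authors' deposited table. Adjusted over the list alone, 12 were higher and 1 lower. The median log2 ratio of its 20 expressed members was 0.37, at percentile 100 of 10000 random lists of matched expression, and their mean was 0.84.

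Other genes of the same list, fixed in advance, did not pass the test. Rora, a nuclear receptor gene in a locus shared with another gene row, was at 14.6 and 18.3 FPKM, with an adjusted p of 0.25 in the authors' deposited table. Il1r1, the IL-1 receptor, was at 12.7 and 14.0 FPKM (adjusted p 0.75 in the authors' deposited table), and Csf2, which encodes GM-CSF, at 11.6 and 9.32 FPKM (0.45). Il10 was listed at 0.148 and 0.602 FPKM, a level at which a 4.07-fold ratio had an adjusted p of 0.20 in the authors' deposited table. By mm10 positions in that table, Il17a spans chromosome 1 from 20730905 to 20734496 and Il17f from 20777146 to 20784270. Ccl20 lies on chromosome 1 from 83116766 to 83119167 and Il22 on chromosome 10 from 118204964 to 118210046. Aqp3 lies on chromosome 4 from 41092724 to 41098183. Each interval is a whole gene with its introns, and the values sum over its transcripts.

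**Figure D2:**
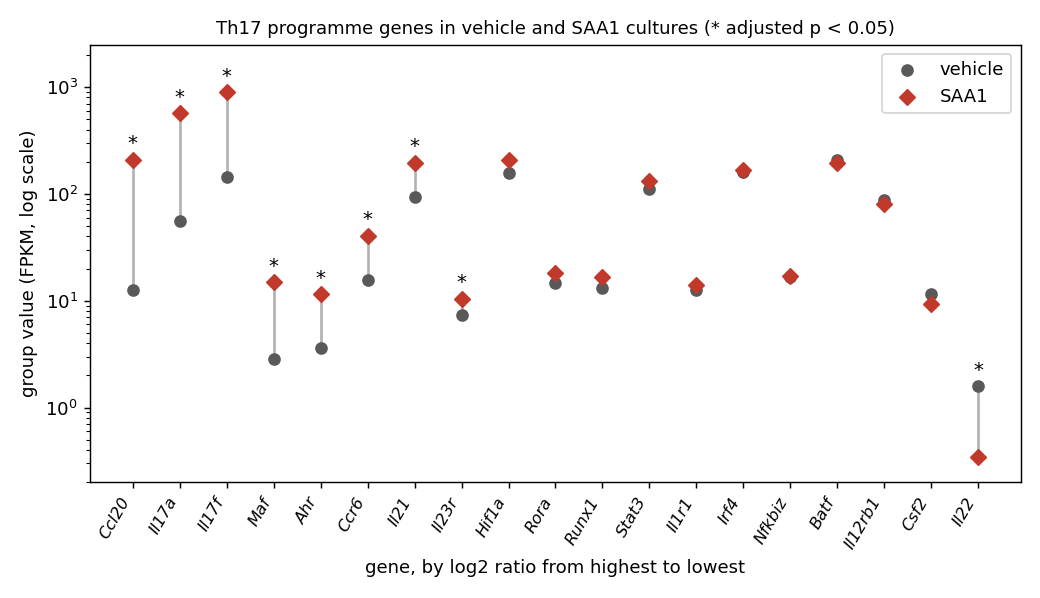
The authors' group values in FPKM, on a log axis, are drawn for 19 of the 20 expressed members of the Th17 list in vehicle (grey circles) and SAA1 (red diamonds) cultures, ordered by log2 ratio and joined by a grey line, with a star where the adjusted p was under 0.05. Stars mark 8 genes that were higher with SAA1, led by Ccl20 at 12.7 and 209 FPKM, and Il22, the only starred gene that was lower.

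Genes tied to the less inflammatory form of Th17 cells were higher as a group with SAA1. Of 8 tested members of the list of non-pathogenic Th17 genes, 5 were called higher and 0 lower by the authors' deposited table. Adjusted over the list alone, 6 were higher. Ahr, the aryl hydrocarbon receptor, rose from 3.58 to 11.5 FPKM (log2 ratio 1.69 ± 0.22), and Ikzf3, the transcription factor Aiolos, from 1.51 to 5.49 FPKM (1.86 ± 0.27). Maf and Il1rn, given above, were also among the 5, as was Cd5l, named to complete the count, from 133 to 255 FPKM. Il10, 1 of the 3 members not called, stayed under 1 FPKM in both groups and so is outside the median. The median of the list's 7 expressed members was 1.80, at percentile 100 of the random lists. Of the 8 members, 5 also stand in other lists.

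Genes tied to the pathogenic form went both ways. Of 16 tested members, 3 were called higher and 2 lower by the authors' deposited table, or 4 and 3 adjusted over the list alone. Cxcl3, a neutrophil-attracting chemokine, rose from 6.16 to 11.5 FPKM and Il7r, the IL-7 receptor, from 1.67 to 2.88 FPKM. Casp1, the protease that activates IL-1β, fell from 19.4 to 9.21 FPKM (log2 ratio -1.07 ± 0.24), beside Il22. The list's median of 0.07 lay at percentile 91.3 of the random lists, and its mean was -0.11. Over its 12 members with at least 5 FPKM the median was 0.14 at percentile 98.4, which stood apart as higher. Over 30 tested cytokines and chemokines, 7 were higher and 3 lower by the authors' deposited table, and 7 and 4 adjusted over the list alone. Their median was 0.03, at percentile 86.0. Over members with at least 5 FPKM it was 0.21 at percentile 100, and the mean of 0.46 lay at percentile 98.6, both apart as higher.

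Genes of the Th1 lineage had a lower median than random lists, with a single call. Cxcr3, the chemokine receptor typical of Th1 cells, fell from 21.8 to 11.02 FPKM (log2 ratio -0.98 ± 0.24) and was the only one of 12 tested Th1 genes called by the authors' deposited table. Adjusted over the list alone, 4 were lower. Tbx21, which encodes the Th1 factor T-bet, was at 22.3 and 18.5 FPKM (adjusted p 0.37 in the authors' deposited table) and Ccl5 at 4.49 and 1.66 FPKM (0.065). The Th1 median of -0.25 lay at percentile 0.26, but at percentile 17.4 with a value of -0.10 over members with at least 5 FPKM, and the mean of -0.24 at percentile 5.77, neither of which stood apart. Of 5 tested Th2 genes, 1 was called in the authors' deposited table, Gata3, the lineage factor, which fell from 1.36 to 0.687 FPKM (adjusted p 0.020). Adjusted over the list alone, 2 Th2 genes were higher and 1 lower, and the median was -0.07 at percentile 33.0. Over the 3 Th2 members with at least 5 FPKM it was 0.34 at percentile 99.3, which stood apart as higher. Ccr4 and Ccr8, chemokine receptors of that list, were at 15.8 and 20.05 FPKM and at 19.2 and 26.2 FPKM.

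Genes of regulatory T cells included large increases. Ctla4, the inhibitory receptor, rose from 299.6 to 744.9 FPKM (log2 ratio 1.31 ± 0.20), Nt5e, the ectoenzyme CD73, from 0.795 to 4.30 FPKM (2.44 ± 0.32), and Capg, an actin-capping protein, from 122 to 177 FPKM. These 3 were the members called higher among 12 tested by the authors' deposited table, with 0 lower. Adjusted over the list alone, 4 were higher and 1 lower. Foxp3, the lineage factor, in a locus shared with another gene row, was listed at 0.169 and 0.184 FPKM and was not tested. The median of 0.06 lay at percentile 87.5 and the mean of 0.40 at percentile 89.4. Over members with at least 0.1 FPKM the median was 0.19 at percentile 99.5, which stood apart as higher.

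Genes of naive T cells moved in both directions, with 3 of 12 tested members higher and 2 lower by the authors' deposited table, and 4 and 2 adjusted over the list alone. Ccr7 and S1pr1, receptors that guide T cells into and out of lymph nodes, rose from 76.1 to 111 FPKM and from 7.11 to 10.4 FPKM. Lef1, a transcription factor of naive T cells, fell from 67.0 to 47.9 FPKM. Their median was 0.06, at percentile 89.4.

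Early genes of T cell receptor signalling held calls in both directions. Of 19 tested members, 1 was called higher and 4 lower by the authors' deposited table, with the same numbers adjusted over the list alone. Egr3 fell from 12.1 to 4.62 FPKM (log2 ratio -1.39 ± 0.28) and Egr1 from 20.4 to 10.9 FPKM (-0.91 ± 0.22), both transcription factors induced by the receptor. Cd69, an early activation marker, fell from 190.1 to 109.8 FPKM, while Nr4a2, a nuclear receptor of the same class of genes, rose from 11.8 to 19.9 FPKM. The median of -0.07 lay at percentile 20.9.

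Interferon-stimulated genes were lower as a group with SAA1. Of 20 tested members, 0 were called higher and 9 lower by the authors' deposited table, and 0 and 12 adjusted over the list alone. Ifit1 fell from 2.35 to 0.875 FPKM (log2 ratio -1.42 ± 0.35), Ifih1, the RNA sensor MDA5, from 22.7 to 10.7 FPKM (-1.09 ± 0.20), and Oas3 from 5.98 to 2.84 FPKM (-1.07 ± 0.24). Trim30a fell from 14.5 to 8.58 FPKM. The median log2 ratio of the 17 expressed members was -0.72, at percentile 0 of the random lists, and -0.46 with a pseudocount of 1. The 4 expressed myeloid and dendritic cell markers also had a median under that of random lists, which did not hold with the mean over members, and of them Cd74 was called lower and H2-Ab1 higher.

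Transcripts of the NF-kB and serum amyloid A receptor lists showed no call. Of 15 tested NF-kB targets, 0 passed Cuffdiff's test in the authors' deposited table, or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Tnfaip3, a feedback inhibitor, was at 45.5 and 39.6 FPKM and Nfkb1 at 156 and 178 FPKM. Their median of 0.04 lay at percentile 93.4. Of 8 tested genes for SAA receptors and adaptors, 0 were called by the authors' deposited table, where 2 had an unadjusted p under 0.05, and 1 was lower adjusted over the list alone. Their median was -0.06, at percentile 32.7. Tlr2, a receptor reported for SAA, was at 1.59 and 2.16 FPKM (adjusted p 0.34 in the authors' deposited table), Tlr1 at 1.63 and 1.09 FPKM and P2rx7 at 2.70 and 1.45 FPKM. Fpr2 was listed at 0 in both groups. Other members were well expressed, with the receptor Scarb1 at 26.0 and 28.2 FPKM and the adaptor Myd88 at 37.4 and 39.5 FPKM. No gene of the SAA family reached 1 FPKM, and Saa1 and Saa2 were listed at 0 in both groups.

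Targets of STAT3, the factor that acts below the receptors for IL-6, IL-21 and IL-23, had a higher median than random lists, with few calls. Fosl2 rose from 25.8 to 39.0 FPKM and Pim1 from 77.9 to 105 FPKM, which were 2 of 11 tested members called higher, with 0 lower, by the authors' deposited table. Adjusted over the list alone, 3 were higher and 1 lower. The median of 0.25 lay at percentile 99.98, but the mean of 0.20 lay at percentile 97.2 and did not stand apart. Of the 12 genes, 7 also stand in other lists.

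Metabolic lists held few calls. Of 20 tested glycolysis and hypoxia genes, 3 were called higher and 0 lower by the authors' deposited table, with the same numbers adjusted over the list alone. Slc16a3, a lactate exporter, rose from 86.0 to 128 FPKM, Egln3, an oxygen sensor, from 32.3 to 45.2 FPKM and Bnip3 from 9.63 to 13.9 FPKM. Their median of 0.16 lay at percentile 100. Ddit4, an inhibitor of mTORC1, rose from 99.6 to 145.9 FPKM and was the only call among 16 amino acid and ER stress genes in the authors' deposited table, against 3 higher adjusted over the list alone, with a median of 0.10 at percentile 99.2. Neither the 20 tested cholesterol synthesis genes nor the 24 cell cycle genes held a call in the authors' deposited table or adjusted over the list alone, and 3 and 1 had an unadjusted p under 0.05. Their medians were -0.11 at percentile 3.89 and 0.04 at percentile 96.8. Mki67, a marker of dividing cells, was at 32.3 and 37.7 FPKM, and Insig1, a regulator of cholesterol synthesis, at 76.1 and 57.4 FPKM.

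Transcripts that identify T cells were present in both groups, and most markers of other blood cells were under 1 FPKM. Of 12 tested T cell identity genes, Thy1 rose from 66.0 to 96.8 FPKM and Cd3e fell from 39.1 to 28.2 FPKM, each called by the authors' deposited table and adjusted over the list alone, and the median was -0.10 at percentile 7.60. Among myeloid and dendritic cell markers, 4 of 23 reached 1 FPKM. H2-Ab1, an MHC class II chain, rose from 4.598 to 10.01 FPKM and Cd74, the class II invariant chain, whose locus holds another gene row, fell from 19.4 to 10.9 FPKM. They were the only calls among 6 tested myeloid markers in the authors' deposited table, and the only ones adjusted over the list alone. The median of the 4 was -0.33 at percentile 1.84. Ctss, a lysosomal protease and the most abundant of these markers, was at 37.2 and 34.5 FPKM. Lyz2 was at 0.178 and 0.0261 FPKM, and C1qa was listed at 0 in both groups.

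Of 5 tested markers of CD8 and natural killer cells, 0 were called by the authors' deposited table or adjusted over the list alone and 1 had an unadjusted p under 0.05, with a median of -0.06 at percentile 34.8 and a mean of 0.02. Cd8b1 was at 4.32 and 4.24 FPKM and Nkg7 at 33.5 and 31.4 FPKM. Of 3 tested B cell markers, 0 were called by the authors' deposited table, where 1 had an unadjusted p under 0.05, and 1 was lower adjusted over the list alone. Only Ebf1, at 1.49 and 0.811 FPKM, reached 1 FPKM. The 7 of 8 neutrophil markers and the 4 of 8 red blood cell markers found by symbol in the table stayed below 1 FPKM in both groups. S100a9 was listed at 0, as was Hba-a2, in a locus shared with another gene row.

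**Figure D3:**
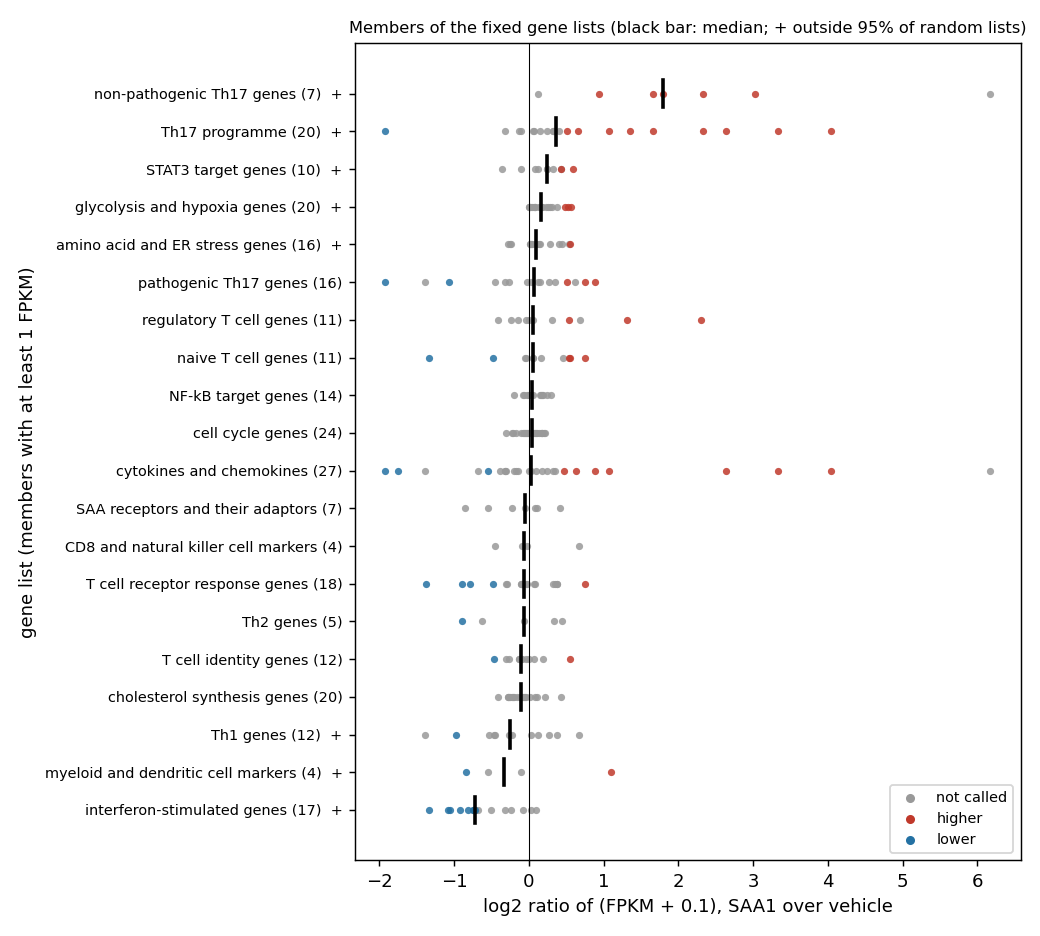
For each fixed list with at least 3 expressed members, points show every member with at least 1 FPKM in either group by its log2 ratio of SAA1 over vehicle after adding 0.1 FPKM, coloured red where called higher, blue where called lower and grey where not called, and the black bar is the median. A plus sign marks the 8 of 20 lists whose median lay outside 95% of random lists, from non-pathogenic Th17 genes at 1.80 to interferon-stimulated genes at -0.72.

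Of 20 lists with enough expressed members, 8 lay outside the middle 95% of random lists, 5 higher and 3 lower. The rate of 5% holds for lists of unrelated genes only. These lists share members, 16 of 22 genes for the Th17 list, so the 8 are not independent and cannot be set against that rate. The percentiles describe these libraries, since genes are not replicates. The Th1, STAT3 target, glycolysis, amino acid stress and myeloid lists no longer stood apart when the mean over members replaced the median. The p-values of the authors' deposited table come from a test of 2 libraries against 2. The labels do not say that libraries came from separate cultures or animals, so any spread behind these p-values may be technical. The implied SE was 0.200 for each of Tnf, Cdk1 and Cd69, which are unlike genes that are well expressed. An SE so alike across genes is not read here as each gene's own spread between libraries. With a normal p of the deposited statistic, an alternative chosen after the data were seen, 247 genes were called in place of 749, and the adjusted p became 0.081 for Il22 and 0.44 for Il23r.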

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

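The normal p, the removal of shared loci and the removal of microRNA and small nucleolar RNA rows were chosen after the data were seen. No paired analysis was possible because the table gives a single value per group; for the same reason no replicate could be left out, and the alternatives for counts or for FPKM per library were not run. Depth is unknown, so what it limits cannot be given. Counts of called genes stayed within 1.5 times of 749, 456 higher and 293 lower under the other settings, such as an adjusted p under 0.1 (1011), at least 1 FPKM (701) or no shared loci (674). These settings all use the deposited p. Centring and the recomputed adjustment over all tested genes could not change the 749. At an adjusted p under 0.01 there were 436 calls, 283 higher and 153 lower, by the stricter threshold itself. A 1.5-fold minimum left 187 lower. A normal p of the deposited statistic gave 247 calls, 155 higher and 92 lower, and 235 of the 247 were also called as deposited. The deposited and the normal p differ for the same statistic, and the cause was not tested.

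The settings could not turn the sign of a called gene, and none of the 8 lists that stood apart in the report changed sign. Other medians did: Th2 at 5 FPKM and at 0.1 FPKM (0.04), SAA receptors at 5 FPKM (0.08), and with the mean the pathogenic Th17 (-0.11) and CD8 and natural killer (0.02) lists. Of 92 named genes with a ratio, 57 were called, and 10 of them lost the call at an adjusted p under 0.01, 11 at the 1.5-fold minimum and 17 with the normal p, while 9 others gained it at 0.1. The interferon median stayed apart with a pseudocount of 1 but moved to -0.46 from -0.72, and the Th17 mean was 0.84 against a median of 0.37. The myeloid median, over 4 genes, no longer stood apart with a pseudocount of 1 (-0.22), at least 5 FPKM (-0.11), at least 0.1 FPKM (-0.22) or the mean (-0.10). At 5 FPKM the Th1 median (-0.10) also lost its place, and the pathogenic Th17 (0.14), Th2 (0.34, against -0.07 before) and cytokine (0.21) medians stood apart as higher, with fewer members in each. The regulatory T cell median did so at 0.1 FPKM (0.19). Unmatched random lists ended the call of amino acid and ER stress genes (0.10). With the mean, 4 lists stood apart in place of 8: besides the myeloid list, Th1 (-0.24), STAT3 target (0.20), glycolysis (0.20) and amino acid stress genes (0.13) did not, and cytokines did (0.46). The cause was not tested for the lists.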

Other observations

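The ligand, guanylate-binding protein and aryl hydrocarbon receptor lists and the tests in this part were chosen after the data were seen, except that the targets of that receptor and the correlation with pseudogene copies were tested before their values had been looked at. The interferon, NF-kB, myeloid and glycolysis lists were fixed earlier. Further ligands of the TNF and B7 families, by which immune cells signal to each other, were called lower besides Tnfsf8 and Tnfsf4. In a list of 15 expressed ligands, drawn up because some had fallen and so not a test of the family, 8 were lower and 2 higher by the authors' deposited table. Cd80 fell from 12.3 to 4.61 FPKM, Cd70 from 19.7 to 8.74 FPKM, Pdcd1lg2 from 16.3 to 7.85 FPKM and Cd274, which encodes PD-L1, from 30.7 to 15.999 FPKM. Tnfsf10 and Cd40lg fell as well, from 1.30 to 0.762 FPKM and from 50.7 to 35.5 FPKM. Lta rose from 97.3 to 151 FPKM and Ltb from 76.2 to 105 FPKM.

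Guanylate-binding proteins, GTPases of cell-autonomous defence, include Gbp2 and Gbp3 of the interferon list. Of 7 expressed members, 4 were called lower by the authors' deposited table, those 2 among them. Gbp5 fell from 6.40 to 3.48 FPKM and Gbp7 from 1.01 to 0.421 FPKM. Irf8, a transcription factor of the interferon regulatory family, went the other way and rose from 8.45 to 28.5 FPKM. Socs2, a suppressor of cytokine signalling, rose from 1.38 to 5.78 FPKM, and Stab1 from 0.566 to 3.15 FPKM in a locus shared with Nt5dc2, so both values are uncertain.

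Interferon-stimulated genes were lower with SAA1, 9 of 20 tested, and 4 expressed myeloid and dendritic cell markers had a median of -0.33. Against scatter of weakly expressed genes as the whole cause, the 7 interferon genes with a mean of at least 5 FPKM over both groups had a median log2 ratio of -0.32, at percentile 0.1 of random lists. The 22 myeloid markers found by symbol had a median of 0.159 FPKM in the vehicle cultures, with Lyz2 at 0.178 and C1qa at 0. That median joins markers of several cell types, and Ctss and Cd74 lay far above it. It argues only against a loss of cells that express most of these markers, for Gbp2, Ifih1 and Trim30a. These are the called genes with a mean of at least 5 FPKM, and each of them lost 5.90 FPKM or more. For the 6 weaker called genes, the smallest loss of which was 0.401 FPKM, that explanation stays open when they are judged as a set. For Cd74, which fell from 19.4 to 10.9 FPKM, the median of 0.159 FPKM likewise argues only against a loss of cells that express most of the 22 markers. H2-Aa and H2-Eb1, other class II markers of the list, were at 0.440 and 0.813 FPKM in the vehicle cultures. H2-Ab1 rose from 4.598 to 10.01 FPKM and Ctss was at 37.2 and 34.5 FPKM. The value of Cd74 is uncertain because its locus holds another gene row. A response of the T cells to SAA1, and a difference between cultures or libraries other than SAA1, were not tested.

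Ahr rose from 3.58 to 11.5 FPKM, its repressor Ahrr from 0.383 to 1.12 FPKM and its target Cyp1b1 from 0.344 to 1.08 FPKM. A candidate explanation is a general rise of targets of this receptor. Other targets had a median log2 ratio of 0.27, at percentile 90.1 of random lists, over 3 expressed genes, and 0 of them were called by the authors' deposited table, so a general rise and a change of a few genes cannot be told apart with so few. Cyp1a1 was at 0.935 and 1.15 FPKM, Tiparp, in a locus shared with another row, at 6.71 and 8.30 FPKM and Nfe2l2, the most abundant of the 3, at 15.2 and 14.9 FPKM.

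Gapdh, among the most abundant transcripts of most cells, was listed at 0.958 and 1.18 FPKM, and Rpl28, a ribosomal protein gene, at 0.813 and 0.821 FPKM. Weak glycolysis is argued against by the other 19 glycolysis and hypoxia genes, whose median in the vehicle group was 78.9 FPKM. Reads shared with pseudogene copies, and then not counted, may account for part of it, since Gapdh has 77 near-identical pseudogenes and, across 75 ribosomal protein genes, more copies went with a lower FPKM (Spearman's rho -0.455, two-sided permutation p = 3.0e-05, across genes, which are not independent replicates). The median was 28.1 FPKM for the 37 genes with over 5 copies and 223 FPKM for the 38 with fewer copies or 5, yet 15 of the former and 10 of the latter were under 20 FPKM (Fisher's exact test, two-sided p = 0.23). The negative rho met the prediction set beforehand for this cause, and the split at 20 FPKM was chosen after the data were seen. Rpl28 has 4 copies, Rpl24 3 and Rpl10a 1, the latter pair at 4.16 and 4.21 FPKM in the vehicle group. The low values thus stay without a settled cause.

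The NF-kB list, of interest because SAA1 can act through receptors that signal to NF-kB, had a median log2 ratio of 0.0417 over 14 genes, at percentile 93.4. Il9 was at 0.239 and 24.4 FPKM, a log2 ratio of 6.67 that was not called (adjusted p 0.49 in the authors' deposited table), although the normal p of its statistic gave an adjusted value of 0.0017. At a single locus on chromosome 10, Amd2 was at 12.4 and 0.0378 FPKM and the row named Amd1,Amd2 at 0.0890 and 11.1 FPKM, neither called. Reads there could belong to either row, so these opposite values are uncertain and are not read as a change of either gene.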
